A study of Homo sapiens with 16 samples.

How the data were processed

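Chromatin immunoprecipitation followed by sequencing was used to compare HCT116, a colorectal carcinoma cell line, with DKO, its derivative in which the DNA methyltransferase genes DNMT1 and DNMT3B are disrupted. The series held 16 samples: 14 immunoprecipitated libraries, 1 per cell line for each of 7 targets, and 2 input libraries. The targets were CTCF, the cohesin subunits RAD21 and SMC1, histone H3 acetylated at lysine 27 (H3K27Ac), RNA polymerase II phosphorylated at serine 5 (Pol2Ser5) or serine 2 (Pol2Ser2) of its C-terminal repeat, and total RNA polymerase II (TotalRNAPol2). Samples were grouped by cell line and target as their titles give them. For the TotalRNAPol2 libraries the title names total polymerase while the antibody label names Pol2Ser5, and the grouping followed the title. The input libraries were not used here.

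Reads were aligned with BWA to the human genome build hg19, per the submitters' processing notes, which also name MACS2 for every target except TotalRNAPol2. Versions and peak thresholds are not given in the sources used here. Each of the 7 deposited tables lists the regions called in DKO only, in HCT116 only or in both lines, with 1 row per region, per the file headers. The read signal of each line is given as a normalized read density, a signal that the authors normalized, per the file headers. The column M is a log2 ratio of the DKO over the HCT116 density and the column A is their mean log2 density, both deposited by the authors. M equalled the log2 ratio of the density columns within 0.001 in every row of the 7 tables. Levels were compared only within a table, since each table was normalized separately. A p-value per region is given in the authors' deposited table. It equalled the binomial probability of the rounded densities at equal odds, divided by 2, within 0.001 on the log10 scale, in at least 99.7% of rows of every table. It thus follows the probability of the exact pair of densities, not of a difference at least as large. Of the regions with M within 0.1 of 0, between 13.1% (Pol2Ser2) and 90.2% (SMC1) had a p-value under 0.05 in the authors' deposited table. The deposited p was used only in 1 alternative filter.

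The reads behind each density were recovered from M and A. In every table the log2 ratio of whole counts equalled M plus a straight line in A, and 100% of the recovered values were whole within 0.05. The smallest recovered value was 1 in every library, so 1 was taken to have been added to each read count. The counting window that fitted was 1 kb for CTCF, RAD21 and SMC1 and 2 kb for the other targets. The line had a slope of 0.33 for Pol2Ser2 and 0.32 for TotalRNAPol2, and between -0.13 and 0.06 for the other targets, so for these polymerase tables the scaling between the lines changed with the level of a region. The centring makes M close to 0 at regions called in both lines, and a change shared by all such regions would not be seen. Total library sizes were not used here, and depth is given as reads per counting window. The median reads per region in DKO and HCT116 were 55 and 36 for CTCF, 46 and 30 for RAD21, 53 and 35 for SMC1, 78 and 94 for H3K27Ac, 43 and 23 for Pol2Ser5, 24 and 34 for Pol2Ser2, and 74 and 50 for TotalRNAPol2. Neighbouring regions can share a counting window: between 40.1% of CTCF regions and 79.6% of H3K27Ac regions had another region's midpoint within 1 window.

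A region was called higher in DKO at M of 1 or more and higher in HCT116 at M of -1 or less, a 2-fold difference, and similar at M within 0.5 of 0. With 1 library per line and target there was no replicate check, and no test between the lines was made. The 95% interval of M is the exact Clopper-Pearson interval from the reads of both libraries, a share has a Wilson 95% interval, and a median over regions has a 95% interval from order statistics. All of them cover counting error or the spread of regions in these libraries only, since reads made by PCR are not independent molecules and regions are not replicates. Where a library had 0 reads, the fold was computed against a floor of 3 reads in that library and is a lower bound at that floor. The exact 95% interval of M reaches somewhat smaller differences at these regions. The number of regions expected past 2-fold from counting error was the mean of 20 simulated tables in which each region's reads were divided between the libraries as the authors' line predicts. Regions of different tables were matched when they shared at least 1 bp, and the match with the longest overlap was used. Spearman correlations of M were computed across matched regions for all 21 pairs of targets, with intervals from 100 resamplings of chromosomes. Positional shifts were measured as medians of regions called in both lines in 2 Mb bins that held at least 8 such regions in at least 6 tables, and as segments in which a library had no reads in windows with at least 30 reads in the other line. The recovery of counts and the intervals were tested on simulated data with the real levels of each table: 100% of counts were recovered in each table, and the intervals covered the true value in 95.8% to 96.3% of regions. The simulated reads followed the same line, window and binomial counting. The result thus checks the code and not whether the real reads follow that model. Of 200 regions changed 4-fold, all drawn from above the table's median A, between 98.5% (Pol2Ser2) and 100% were called at the 2-fold rule. Recovery of changes at lower levels was not tested.

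Regions are named by hg19 coordinates as the tables give them. The groups, the rule for named regions and the first set of alternatives below were fixed before the data were examined. Named are the 5 with the highest and the 5 with the lowest M of each target among regions whose higher density was at or above the table's median, and likewise the 5 with the highest and lowest mean M of CTCF, RAD21 and SMC1 among CTCF regions at which all 3 differed 2-fold in the same direction and met that density rule in their own table. Regions were not assigned to genes, because the gene table at hand follows another build (GRCh38), so gene lists, the loci of the disrupted genes and sequence context were not analysed here. Chromosome Y was left out of the named regions and positional summaries. The first set of alternatives was other fold thresholds, a density filter, a filter on the deposited p, recentring on all regions or on chromosome medians, regions called in both lines, autosomes only, and other definitions of overlap. Chosen after the data were seen were constant centring (the log2 ratio of recovered counts minus its median over regions called in both lines) and 1 region per counting window. Removal of the tables' median shift in each 2 Mb bin (the median of their bin medians) was also chosen then. So were, with their alternatives, the medians of the polymerase tables at H3K27Ac regions and of RAD21 and SMC1 at CTCF regions and the joint count of acetylation and polymerase at H3K27Ac regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.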

Results

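The series asked how DNA methylation, through CTCF and the cohesin complex, bears on the choice of polyadenylation site, and compared HCT116 cells with DKO cells by chromatin immunoprecipitation of 7 targets. Polyadenylation itself was not analysed here. The 7 tables held between 149589 regions (Pol2Ser5) and 236942 regions (Pol2Ser2). The share of regions that the authors called in both lines was 43.6% for CTCF, 38.2% for RAD21, 34.1% for SMC1 and 31.7% for H3K27Ac, and it was 20.1% for Pol2Ser5, 18.3% for Pol2Ser2 and 20.2% for TotalRNAPol2. M is the log2 ratio of the authors' normalized densities, DKO over HCT116. Each line had 1 library per target, so no difference could be set against a spread between replicates.

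CTCF, the zinc finger protein that binds insulators and domain boundaries and whose binding can be blocked by methylation of its site, was higher in DKO at many more regions than it was lower. Of 171693 CTCF regions, 34479 (20.1%) were at least 2-fold higher in DKO and 10867 (6.33%) at least 2-fold higher in HCT116, a ratio of 3.17, while 77264 (45.0%) were similar. Counting error alone gave 538 and 484 such regions. Regions higher in DKO had a median of 64 reads in DKO and 18 in HCT116, and 86.0% of them were called in DKO only. The highest was chr9:976133-978059, with 263 reads in DKO and 2 in HCT116 (M 6.25, 95% counting interval 4.96 to 9.88). There H3K27Ac (M 2.50), Pol2Ser5 (M 3.65) and TotalRNAPol2 (M 3.71) were higher in DKO as well. At chr3:96531590-96534331 CTCF had 495 and 5 reads (M 6.24, 5.27 to 8.13), and at chr16:49315841-49316757 it had 262 and 2 (M 6.24, 4.95 to 9.88). The lowest region, chr20:31377206-31379363, had 431 reads in HCT116 and 0 in DKO, at least 171-fold lower at the floor of 3 reads. The exact 95% interval of M there reached up to -7.11. This region lies in an interval of chromosome 20 in which all 34 regions of 6 tables had 0 reads in DKO. Missing DNA cannot be told apart from missing binding there. Among regions whose higher density was at or above the table's median, the next 4 all lay on chromosome X. They included chrX:27936849-27937346 with 1 read in DKO and 73 in HCT116 (M -5.53, -11.83 to -3.99). Among them, chrX:28608395-28608862 and chrX:28613315-28614161 lie in a segment where 16 of the 66 regions of 7 tables had no DKO reads. Regions higher in DKO made up 76.0% of all CTCF regions past 2-fold. This share was 56.8% with M recentred on all regions, 58.2% with chromosome medians removed and 83.5% under constant centring. Among regions called in both lines the counts were 4818 higher in DKO and 3226 higher in HCT116.

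**Figure D1:**
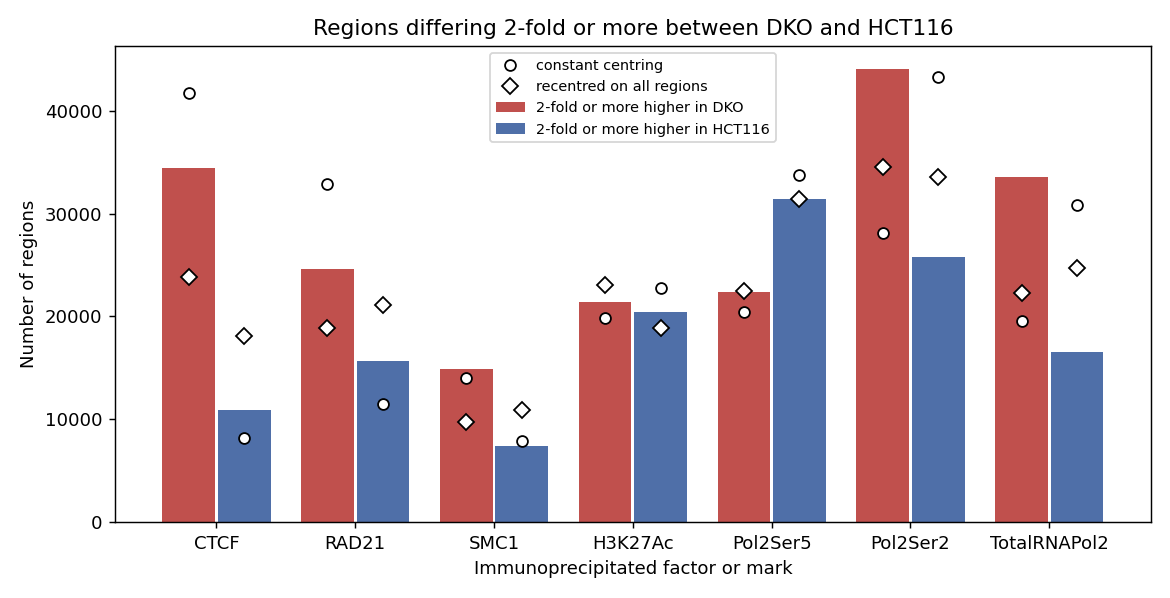
Bars give the number of regions at least 2-fold higher in DKO (red) or HCT116 (blue) for each target from the deposited M; circles give the same counts under constant centring and diamonds after recentring on all regions. CTCF had more regions higher in DKO under each of these, 34479 against 10867 as deposited, while the order turned over for Pol2Ser2 and H3K27Ac under constant centring, for RAD21 and SMC1 after recentring, and for TotalRNAPol2 under both.

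The cohesin subunits RAD21 and SMC1, parts of the ring complex that holds chromatin loops at CTCF sites, differed at fewer regions. RAD21 was at least 2-fold higher in DKO at 24621 of 180061 regions (13.7%) and in HCT116 at 15657 (8.70%). SMC1 was higher in DKO at 14923 of 159358 regions (9.36%) and in HCT116 at 7439 (4.67%). Counting error alone gave 947 and 737 regions for RAD21 and 482 and 393 for SMC1. The highest RAD21 region, chr4:67035058-67035532, had 75 reads in DKO and 0 in HCT116, at least 15.4-fold higher, and CTCF there had an M of 3.20. The highest SMC1 region, chr22:48972241-48972405, had 75 reads and 1 read (M 4.97, 3.43 to 11.27), with an M of 4.38 for CTCF and 2.39 for RAD21. The lowest region of both subunits was the chromosome 20 site without CTCF reads in DKO: RAD21 had 174 reads in HCT116 and 0 in DKO (at least 89.2-fold lower), and SMC1 had 151 and 0 (at least 61.0-fold lower). As for CTCF, missing DNA cannot be told apart from missing binding at this site. The majority of regions past 2-fold was higher in DKO for RAD21 (61.1%) and SMC1 (66.7%) as deposited, but the majority turned to HCT116 with M recentred on all regions (47.2% and 47.0% higher in DKO) or with chromosome medians removed (46.9% and 47.9%), and constant centring gave 74.1% for RAD21. Among regions called in both lines RAD21 turned as well, with 3465 regions higher in DKO against 3989 higher in HCT116, while SMC1 had 1224 against 600.

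CTCF and cohesin differed together. Of the 34479 CTCF regions higher in DKO, 38.4% (37.9% to 38.9%) overlapped both cohesin subunits, against 52.4% (52.0% to 52.7%) of similar CTCF regions and 33.7% (32.9% to 34.6%) of those higher in HCT116, but the order of the first 2 shares turned over at a 4-fold threshold, where 55.9% of CTCF regions higher in DKO overlapped both. Where both subunits were present at a CTCF region higher in DKO, RAD21 was also at least 2-fold higher in 50.7% (49.9% to 51.6%), SMC1 in 42.9% (42.1% to 43.8%) and both in 32.4% (31.6% to 33.2%). Of the similar CTCF regions that overlapped both subunits, both were higher in DKO in 0.756% (0.676% to 0.845%), and at a 4-fold threshold these joint shares were 9.76% and 0.0099%. Both were higher in HCT116 in 17.4% (16.2% to 18.7%) of the 3667 CTCF regions higher in HCT116 that overlapped both, and in 2 of the 13239 CTCF regions higher in DKO that did. The median M at CTCF regions higher in DKO was 0.92 (0.90 to 0.93) for RAD21 and 0.85 (0.84 to 0.86) for SMC1. At similar CTCF regions it was 0.04 and 0.03 as deposited, and these turned to -0.05 and -0.05 with chromosome medians removed, while constant centring gave -0.05 for RAD21 and 0.02 for SMC1. In all, 4292 CTCF regions were higher in DKO together with both subunits and 639 were higher in HCT116 together with both. The balance of these joint counts was taken from the deposited M only. It was not computed with M recentred on all regions, where RAD21 and SMC1 alone turned to a majority higher in HCT116. By mean M the highest was chr3:96531590-96534331, where RAD21 had 326 reads in DKO and 11 in HCT116 (M 4.43, 3.70 to 5.57) and SMC1 had 223 and 13 (M 3.68, 2.98 to 4.72). It was followed by chr18:65182886-65184077, with 432 and 6 CTCF reads (M 5.83), an M of 4.54 for RAD21 and 3.28 for SMC1, and Pol2Ser5 at 5.28. At chr10:7449354-7451908 CTCF (M 5.98), RAD21 (M 3.55) and SMC1 (M 2.93) were higher with no acetylation or polymerase region over it. After the chromosome 20 site, the lowest was chr7:120943484-120944050, where CTCF had 10 and 113 reads (M -3.56, -4.78 to -2.75), RAD21 an M of -3.79, SMC1 of -3.15, TotalRNAPol2 of -2.40 and H3K27Ac of -6.31.

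**Figure D2:**
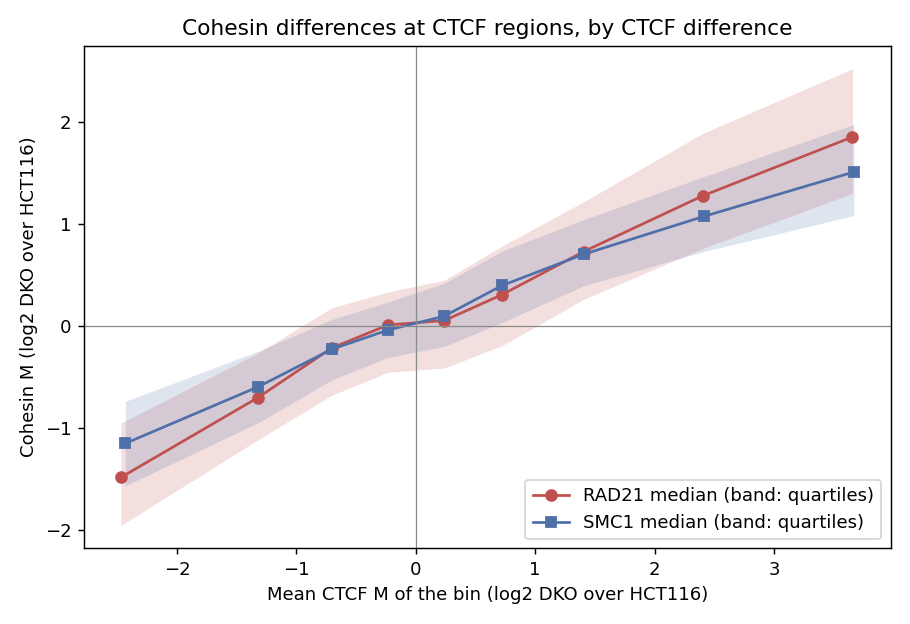
Median M of RAD21 (circles) and SMC1 (squares) at CTCF regions, in bins of CTCF M placed at the bin's mean, with bands from the lower to the upper quartile of regions. RAD21 rose from a median of -1.48 in the lowest CTCF bin to 1.86 in the highest, and SMC1 from -1.15 to 1.51.

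Cohesin also occurred away from CTCF. Of the RAD21 regions that overlapped an SMC1 region, 18684 overlapped no CTCF region and 81040 overlapped one. Without CTCF, both subunits were higher in DKO at 847 sites (4.53%) and in HCT116 at 547 (2.93%). With CTCF these shares were 6.93% and 1.29%. They too were taken from the deposited M only, and other scalings were not computed for them. Among the named regions without CTCF, chr17:56100013-56100793 had 14 SMC1 reads in DKO and 98 in HCT116 (M -3.03, -4.04 to -2.30), with an M of -3.02 for RAD21 and -2.94 for H3K27Ac.

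Acetylation and polymerase differed with CTCF to unequal degrees. At CTCF regions higher in DKO the median M was 1.34 (1.31 to 1.35) for TotalRNAPol2, 0.94 (0.92 to 0.97) for Pol2Ser5, 0.78 (0.76 to 0.80) for Pol2Ser2 and 0.22 (0.20 to 0.23) for H3K27Ac, the mark of active promoters and enhancers. At similar CTCF regions it was 0.17, 0.01, 0.33 and -0.05, and with chromosome medians removed 0.06, 0.11, 0.19 and, turning over, 0.03, while that of H3K27Ac at CTCF regions higher in DKO became 0.36. At CTCF regions higher in HCT116 it was -0.85 for TotalRNAPol2, -0.78 for Pol2Ser5, -0.23 for Pol2Ser2 and -0.86 for H3K27Ac, with chromosome medians removed it was -0.49 for both Pol2Ser5 and H3K27Ac, and under constant centring it was -0.47 for Pol2Ser2 and -1.35 for TotalRNAPol2. TotalRNAPol2 was at least 2-fold higher in 65.1% (64.3% to 66.0%) of the 12170 CTCF regions higher in DKO that it overlapped, and H3K27Ac in 22.9% (22.2% to 23.6%) of 14686. Of CTCF regions higher in DKO, 55.8% (55.3% to 56.3%) overlapped an acetylation or polymerase region, against 49.7% (49.4% to 50.1%) of similar ones. The difference between the medians at CTCF regions higher in DKO and at similar ones stayed above 0 for each of these 4 targets within 5 kb, with chromosome medians removed, at or above the median density and under constant centring.

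**Figure D3:**
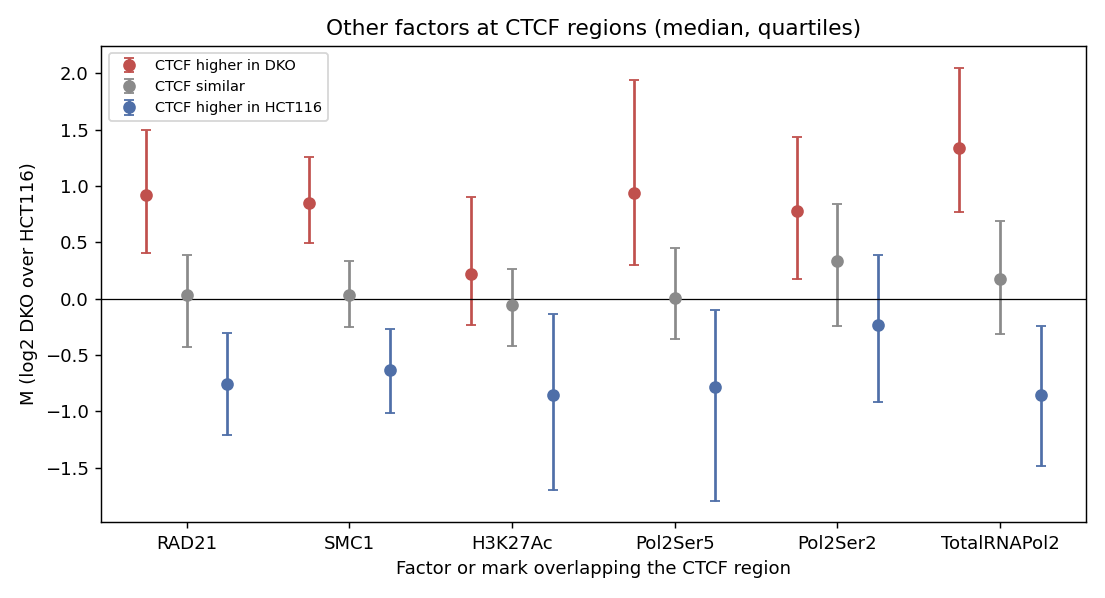
Median M of the other 6 targets where they overlapped CTCF regions higher in DKO (red), similar (grey) or higher in HCT116 (blue), with bars from the lower to the upper quartile of regions. At CTCF regions higher in DKO the medians ran from 0.22 for H3K27Ac to 1.34 for TotalRNAPol2.

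H3K27Ac itself differed at nearly as many regions in each direction. It was at least 2-fold higher in DKO at 21454 of 195421 regions and in HCT116 at 20404 (10.4%), while counting error alone gave 58 and 81. The order turned over under constant centring (19859 and 22736) and at a 1.5-fold threshold (38228 and 41339). The highest region, chr9:25677001-25679237, had 717 reads in DKO and 3 in HCT116 (M 7.77, 6.63 to 10.46), with Pol2Ser5 at 5.34, TotalRNAPol2 at 5.29 and CTCF at 3.04. At chr10:132098236-132100493 (585 and 5 reads, M 6.88, 5.91 to 8.77) all 7 targets were higher in DKO, from 2.48 for RAD21 to 6.07 for TotalRNAPol2 among the others. The lowest region, chrX:28605498-28610799, had 202 reads in HCT116 and 0 in DKO, at least 51.2-fold lower, and chr7:120940733-120944768 had 484 and 4 (M -6.31, -8.51 to -5.27). The chromosome X region lies in the segment where 16 of the 66 regions of 7 tables had no DKO reads.

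Polymerase differed with acetylation. At H3K27Ac regions higher in DKO the median M was 1.65 (1.62 to 1.69) for Pol2Ser5, 1.57 (1.54 to 1.61) for TotalRNAPol2 and 0.92 (0.89 to 0.96) for Pol2Ser2. At H3K27Ac regions higher in HCT116 it was -1.40 (-1.44 to -1.36), -1.05 (-1.07 to -1.03) and -0.42 (-0.46 to -0.38), and at similar H3K27Ac regions it was above 0 as well, at 0.19 (0.19 to 0.20), 0.55 (0.54 to 0.56) and 0.46 (0.45 to 0.47). Of 34272 H3K27Ac regions that overlapped all 3 polymerase tables, all 4 targets were at least 2-fold higher in DKO at 1783 (5.20%) and in HCT116 at 552 (1.61%), under constant centring at 1554 and 681, and among regions called in both lines in all 4 tables at 38 and 36. The medians of the polymerase tables at H3K27Ac regions had the same sign under constant centring, with chromosome medians removed and among regions called in both lines, but at similar regions those of TotalRNAPol2 and Pol2Ser2 fell to 0.21 and 0.26 with chromosome medians removed, and among regions called in both lines all lay nearer to 0. In these, for Pol2Ser5, TotalRNAPol2 and Pol2Ser2 they were 1.08, 0.79 and 0.44 at regions higher in DKO, -1.03, -0.77 and -0.27 at those higher in HCT116, and 0.04, 0.11 and 0.23 at similar ones.

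For the polymerase tables the balance of gains and losses depended on the regions kept (Pol2Ser5) or on the scaling (Pol2Ser2 and TotalRNAPol2). Under each scaling, Pol2Ser5 regions higher in DKO made up between 37.7% and 43.1% of those past 2-fold. Pol2Ser5 was at least 2-fold higher in DKO at 22346 of 149589 regions (14.9%) and in HCT116 at 31457, but the order was reversed among regions at or above the median density (15783 against 8237), with a p under 1e-05 in the authors' deposited table (5836 against 2997) and among regions called in both lines (2104 against 1855). Pol2Ser2, the form found along transcribed genes, was higher in DKO at 44094 of 236942 regions (18.6%) and in HCT116 at 25769 (10.9%), and TotalRNAPol2 at 33515 (20.7%) and 16525 (10.2%) of 162247. With constant centring both orders turned over: regions higher in DKO fell from 63.1% to 39.3% of those past 2-fold for Pol2Ser2 and from 67.0% to 38.9% for TotalRNAPol2, and recentring on all regions gave 50.7% and 47.4%, with chromosome medians removed 51.2% and 49.3%. Constant centring moved the median of all regions by -0.24 for Pol2Ser2 and by -0.29 for TotalRNAPol2, and recentring moved it by -0.26 for CTCF, -0.14 for RAD21, -0.16 for SMC1, -0.17 for Pol2Ser2 and -0.27 for TotalRNAPol2. Single regions differed far more than these shifts. At chr9:21510851-21536675 Pol2Ser2 had 995 reads in HCT116 and 2 in DKO (M -8.01, -11.64 to -6.73) and TotalRNAPol2 had an M of -4.83. These reads are those of its 2 kb counting window, which is shorter than the region, and the region was called in both lines. At chr4:75229600-75236139 Pol2Ser5 had 637 and 12 reads (M -6.40, -7.47 to -5.70), with H3K27Ac at -4.58 and CTCF at -0.59. In the other direction, chr1:53307810-53309763 had 567 Pol2Ser5 reads in DKO and 2 in HCT116 (M 6.82, 5.55 to 10.45), with CTCF at 4.30. The TotalRNAPol2 region chrX:151089131-151093376 had 274 reads in DKO and 3 in HCT116 (M 6.17, 5.02 to 8.87).

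Across overlapping regions, M correlated positively for all 21 pairs of targets. These correlations are across regions of the same 2 cell lines, and regions are not independent replicates. The highest Spearman rho was 0.73 (0.71 to 0.75) for Pol2Ser5 with TotalRNAPol2, followed by 0.71 (0.70 to 0.72) for RAD21 with SMC1 and 0.68 (0.66 to 0.70) for Pol2Ser2 with TotalRNAPol2. Under constant centring this order changed, with Pol2Ser2 and TotalRNAPol2 highest at 0.75 and Pol2Ser5 with TotalRNAPol2 at 0.71. CTCF correlated at 0.60 (0.59 to 0.61) with SMC1, 0.50 (0.48 to 0.51) with RAD21, 0.62 (0.60 to 0.64) with TotalRNAPol2 and 0.29 (0.27 to 0.32) with H3K27Ac. H3K27Ac correlated at 0.61 (0.58 to 0.65) with Pol2Ser5. The lowest was 0.093 (0.070 to 0.115) for RAD21 with Pol2Ser2, and this pair (-0.059) and SMC1 with Pol2Ser2 (-0.010) turned negative among regions called in both lines, where CTCF with RAD21 fell to 0.22 and CTCF with SMC1 to 0.33. Of regions at which RAD21 and SMC1 both passed 2-fold, 99.8% of 8074 had the same direction.

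The median CTCF M ran from -0.21 on chromosome X to 0.60 on chromosome 21, but among regions called in both lines it was 0.15 on chromosome 21 and ran from -0.31 on X to 0.23 on chromosome 20. Over all regions the share of CTCF regions higher in DKO ran from 10.5% (9.58% to 11.5%) on X to 33.7% (31.7% to 35.7%) on 21. In 6 of 865 bins of 2 Mb, every table with enough regions had a median M of at least 0.3 in size in the same direction, and 0 such bins arose in 1000 shufflings of the bins within each table. Between 48 and 54 Mb of chromosome 13 the median M of regions called in both lines was lower in DKO for all 7 targets, from -0.99 (-1.10 to -0.85) for SMC1 to -0.64 (-0.88 to -0.51) for TotalRNAPol2. Between 42 and 48 Mb of chromosome 20 it was higher in DKO for all 7, from 0.40 (0.24 to 0.55) for TotalRNAPol2 to 0.56 (0.49 to 0.62) for RAD21. Of the 6 shared bins, 3 lay in the first segment, 2 at 44 to 48 Mb in the second, and 1 at 240 to 242 Mb of chromosome 2, where all 7 medians were lower in DKO. These segments were chosen after their values were seen.

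**Figure D4:**
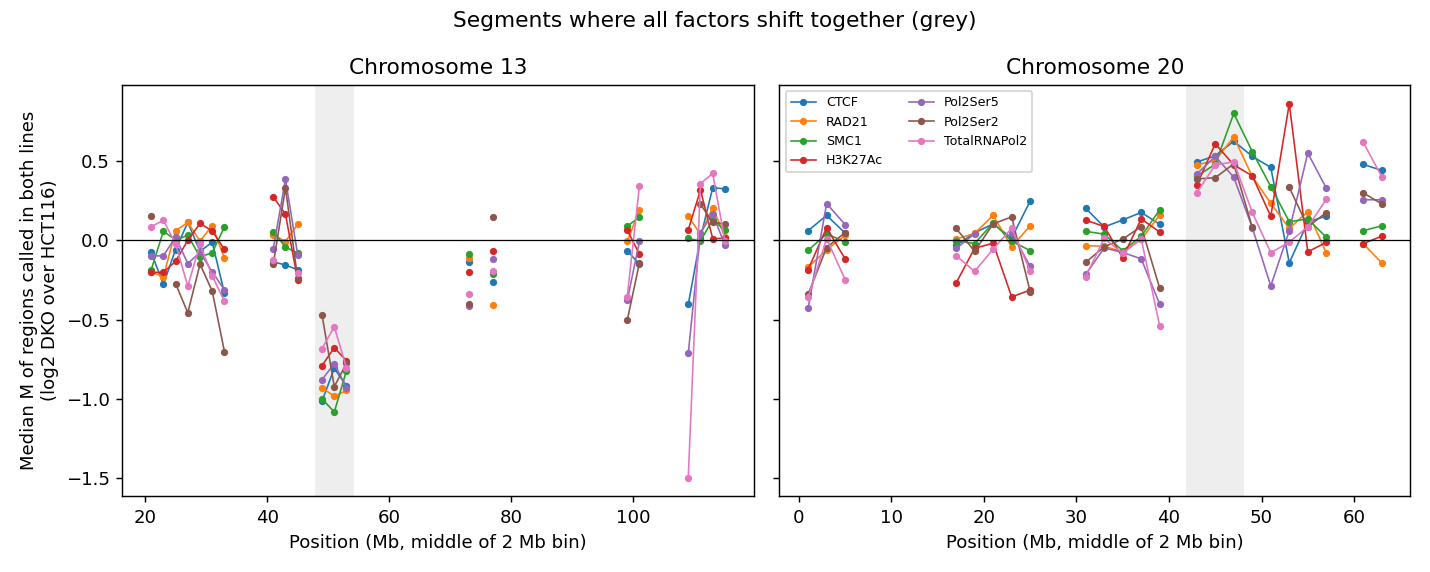
Median M of regions called in both lines in 2 Mb bins along chromosomes 13 and 20, one line per target; bins with too few regions are left blank. In the grey segments all 7 targets lay on the same side of 0, with medians from -0.99 to -0.64 on chromosome 13 and from 0.40 to 0.56 on chromosome 20.

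At a few sites DKO had no reads in several tables. Between 31368726 and 31392574 on chromosome 20, all 34 regions that 6 of the tables hold there had 0 reads in DKO, with up to 431 reads in HCT116 for CTCF, 174 for RAD21, 151 for SMC1, 79 for Pol2Ser2, 74 for TotalRNAPol2 and 35 for Pol2Ser5. DNMT3B, a gene disrupted in DKO, is known to lie on chromosome 20, but regions were not assigned to genes and this interval is not matched to it here. Since the input libraries were not used, missing DNA at such sites cannot be told apart from missing binding. Between 10504004 and 10550553 on chromosome X all 8 regions of 3 tables had 0 DKO reads, with up to 198 H3K27Ac reads in HCT116. Of the 114 segments without DKO reads these and 1 further segment on chromosome X (28515615 to 28821078) involved at least 3 tables, the last with no DKO reads in 16 of the 66 regions that 7 tables hold there, and of the 60 segments without HCT116 reads 0 did.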

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

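Constant centring, 1 region per counting window and removal of the tables' median shift in 2 Mb bins were chosen after the results were seen. So were, with their alternatives, the medians of polymerase at H3K27Ac regions and of RAD21 and SMC1 at CTCF regions and the count of H3K27Ac regions with all 4 targets past 2-fold. Regions higher in DKO outnumbered those higher in HCT116 in 12 of 12 settings for CTCF, the deposited values included, with a ratio from 1.31 to 6.03. They did so in 9 of 12 settings for RAD21, 10 for SMC1, 10 for H3K27Ac, 3 for Pol2Ser5, 10 for Pol2Ser2 and 9 for TotalRNAPol2. Of the CTCF regions, 41.3% were called in DKO only and 15.1% in HCT116 only. All CTCF settings but 1 include such regions, and in that 1, regions called in both lines, the ratio was 1.49. With autosomes only and with the tables' median shift in 2 Mb bins removed, each count of regions stayed within 1.5 times its reported value. Thresholds, filters and smaller sets of regions lower or raise counts by their construction, and for the other changes the cause was not tested. Listed by setting are the counts that moved by more than 1.5 times, the values that moved beyond their interval and those that turned direction. Depth limits single regions most for Pol2Ser2 and Pol2Ser5, whose counts expected from counting error were the highest. Gene lists, sequence context and the regions at the disrupted genes were not run, since regions were not assigned to genes. No paired analysis was possible because each line had 1 library per target.

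At a 1.5-fold threshold, regions higher in DKO numbered 59546 CTCF, 49765 RAD21, 39550 SMC1, 38228 H3K27Ac, 39500 Pol2Ser5, 77522 Pol2Ser2 and 58627 TotalRNAPol2, and those higher in HCT116 24340 CTCF, 34963 RAD21, 20265 SMC1, 41339 H3K27Ac, 48722 Pol2Ser2 and 30363 TotalRNAPol2. The DKO to HCT116 ratio of these counts crossed 1, at 0.925 for H3K27Ac.

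At a 4-fold threshold, regions higher in DKO numbered 8305 CTCF, 3550 RAD21, 936 SMC1, 6391 H3K27Ac, 5973 Pol2Ser5, 9300 Pol2Ser2 and 6956 TotalRNAPol2, and those higher in HCT116 1378 CTCF, 1179 RAD21, 439 SMC1, 5249 H3K27Ac, 11273 Pol2Ser5, 5356 Pol2Ser2 and 2840 TotalRNAPol2. 55.9% of CTCF regions higher in DKO overlapped both cohesin subunits (more than the 52.4% of similar ones, the reverse of the reported order), 9.76% of overlapped CTCF regions higher in DKO had both subunits higher in DKO and 0.0099% of overlapped similar CTCF regions had both subunits higher in DKO.

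Among regions at or above the median density, regions higher in DKO numbered 19044 CTCF, 11774 RAD21, 9081 SMC1, 12707 H3K27Ac and 25702 Pol2Ser2, and those higher in HCT116 4214 CTCF, 7440 RAD21, 1641 SMC1, 9578 H3K27Ac, 8237 Pol2Ser5, 10838 Pol2Ser2 and 6717 TotalRNAPol2. The DKO to HCT116 ratio of these counts crossed 1, at 1.92 for Pol2Ser5. 41.1% of overlapped CTCF regions higher in DKO had both subunits higher in DKO, 63.9% of similar CTCF regions overlapped both subunits and 0.536% of overlapped similar CTCF regions had both subunits higher in DKO. The median M at CTCF regions higher in DKO minus that at similar ones was 1.01 for RAD21, 0.98 for SMC1, 0.29 for H3K27Ac, 0.98 for Pol2Ser5 and 0.38 for Pol2Ser2.

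Among regions with a p under 1e-05 in the authors' deposited table, regions higher in DKO numbered 19280 CTCF, 8513 RAD21, 5918 SMC1, 12481 H3K27Ac, 5836 Pol2Ser5, 5065 Pol2Ser2 and 14732 TotalRNAPol2, and those higher in HCT116 4331 CTCF, 5330 RAD21, 1129 SMC1, 9851 H3K27Ac, 2997 Pol2Ser5, 2015 Pol2Ser2 and 4671 TotalRNAPol2. Crossing 1, the ratio of counts, DKO to HCT116, was 1.95 for Pol2Ser5.

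With M recentred on all regions, regions higher in DKO numbered 9722 SMC1 and 22275 TotalRNAPol2, and those higher in HCT116 18123 CTCF. The DKO to HCT116 ratio of these counts crossed 1, at 0.895 for RAD21, 0.888 for SMC1 and 0.901 for TotalRNAPol2.

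With chromosome medians removed, regions higher in DKO numbered 9754 SMC1 and 21956 TotalRNAPol2, and those higher in HCT116 16929 CTCF. Crossing 1, the ratio of counts, DKO to HCT116, was 0.882 for RAD21, 0.918 for SMC1 and 0.973 for TotalRNAPol2. 41.6% of CTCF regions higher in DKO overlapped both cohesin subunits, 30.1% of overlapped CTCF regions higher in DKO had both subunits higher in DKO and 47.4% of similar CTCF regions overlapped both subunits. The Spearman rho was 0.39 for RAD21 with Pol2Ser5, 0.36 for RAD21 with TotalRNAPol2, 0.46 for SMC1 with Pol2Ser5 and 0.48 for SMC1 with TotalRNAPol2. The median M at CTCF regions higher in DKO minus that at similar ones was 0.98 for RAD21, 0.84 for SMC1, 0.33 for H3K27Ac, 1.02 for Pol2Ser5 and 0.48 for Pol2Ser2. At H3K27Ac regions higher in DKO the median M was 0.69 for Pol2Ser2 and 1.26 for TotalRNAPol2, and at those higher in HCT116 -0.60 for Pol2Ser2 and -1.26 for TotalRNAPol2. At similar H3K27Ac regions it was 0.17 for Pol2Ser5, 0.26 for Pol2Ser2 and 0.21 for TotalRNAPol2.

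Among regions called in both lines, regions higher in DKO numbered 4818 CTCF, 3465 RAD21, 1224 SMC1, 3645 H3K27Ac, 2104 Pol2Ser5, 2400 Pol2Ser2 and 2043 TotalRNAPol2, and those higher in HCT116 3226 CTCF, 3989 RAD21, 600 SMC1, 3231 H3K27Ac, 1855 Pol2Ser5, 2532 Pol2Ser2 and 1923 TotalRNAPol2. The DKO to HCT116 ratio of these counts crossed 1, at 0.869 for RAD21, 1.13 for Pol2Ser5 and 0.948 for Pol2Ser2. The Spearman rho was 0.22 for CTCF with RAD21, 0.33 for CTCF with SMC1, 0.19 for CTCF with H3K27Ac, 0.30 for CTCF with Pol2Ser5, 0.16 for CTCF with Pol2Ser2, 0.38 for CTCF with TotalRNAPol2, 0.63 for RAD21 with SMC1, 0.24 for RAD21 with H3K27Ac, 0.18 for RAD21 with Pol2Ser5, -0.059 for RAD21 with Pol2Ser2, 0.077 for RAD21 with TotalRNAPol2, 0.28 for SMC1 with H3K27Ac, 0.24 for SMC1 with Pol2Ser5, -0.010 for SMC1 with Pol2Ser2, 0.19 for SMC1 with TotalRNAPol2, 0.57 for H3K27Ac with Pol2Ser5, 0.16 for H3K27Ac with Pol2Ser2, 0.41 for H3K27Ac with TotalRNAPol2, 0.32 for Pol2Ser5 with Pol2Ser2, 0.69 for Pol2Ser5 with TotalRNAPol2 and 0.51 for Pol2Ser2 with TotalRNAPol2. At H3K27Ac regions higher in DKO the median M was 1.08 for Pol2Ser5, 0.44 for Pol2Ser2 and 0.79 for TotalRNAPol2, and at those higher in HCT116 -1.03 for Pol2Ser5, -0.27 for Pol2Ser2 and -0.77 for TotalRNAPol2. At similar H3K27Ac regions it was 0.038 for Pol2Ser5, 0.23 for Pol2Ser2 and 0.11 for TotalRNAPol2. All 4 acetylation and polymerase targets were higher in DKO at 38 H3K27Ac regions and in HCT116 at 36. The range of chromosome medians was 0.54 for CTCF, 0.34 for RAD21, 0.20 for SMC1, 0.27 for Pol2Ser5 and 0.39 for TotalRNAPol2.

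Under constant centring, regions higher in DKO numbered 28083 Pol2Ser2 and 19605 TotalRNAPol2, and those higher in HCT116 43305 Pol2Ser2 and 30801 TotalRNAPol2. Crossing 1, the ratio of counts, DKO to HCT116, was 0.873 for H3K27Ac, 0.648 for Pol2Ser2 and 0.637 for TotalRNAPol2. 34.9% of CTCF regions higher in DKO overlapped both cohesin subunits, 30.7% of overlapped CTCF regions higher in DKO had both subunits higher in DKO and 54.2% of similar CTCF regions overlapped both subunits. The Spearman rho was 0.35 for CTCF with Pol2Ser2, 0.59 for CTCF with TotalRNAPol2, 0.35 for RAD21 with H3K27Ac, 0.40 for RAD21 with Pol2Ser5, 0.13 for RAD21 with Pol2Ser2, 0.29 for RAD21 with TotalRNAPol2, 0.37 for SMC1 with H3K27Ac, 0.26 for SMC1 with Pol2Ser2, 0.43 for SMC1 with TotalRNAPol2, 0.56 for Pol2Ser5 with Pol2Ser2 and 0.75 for Pol2Ser2 with TotalRNAPol2. The median M at CTCF regions higher in DKO minus that at similar ones was 1.05 for RAD21, 0.77 for SMC1, 0.19 for H3K27Ac, 0.82 for Pol2Ser5, 0.49 for Pol2Ser2 and 0.80 for TotalRNAPol2. At H3K27Ac regions higher in DKO the median M was 0.82 for Pol2Ser2 and 1.26 for TotalRNAPol2, and at those higher in HCT116 -1.44 for Pol2Ser5, -0.62 for Pol2Ser2 and -1.45 for TotalRNAPol2. At similar H3K27Ac regions it was 0.47 for TotalRNAPol2.

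With 1 region per counting window, regions higher in DKO numbered 11590 H3K27Ac, 12933 Pol2Ser5, 25269 Pol2Ser2 and 18962 TotalRNAPol2, and those higher in HCT116 11532 H3K27Ac, 14900 Pol2Ser2 and 10761 TotalRNAPol2.

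With an overlap of at least 0.5 of the shorter region, 36.3% of CTCF regions higher in DKO overlapped both cohesin subunits, 33.6% of overlapped CTCF regions higher in DKO had both subunits higher in DKO and 50.5% of similar CTCF regions overlapped both subunits.

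With midpoints within 200 bp, 27.9% of CTCF regions higher in DKO overlapped both cohesin subunits, 36.8% of overlapped CTCF regions higher in DKO had both subunits higher in DKO and 41.8% of similar CTCF regions overlapped both subunits.

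With targets within 5 kb of the CTCF region, the median M at CTCF regions higher in DKO minus that at similar ones was 0.71 for RAD21, 0.64 for SMC1, 0.20 for H3K27Ac, 0.68 for Pol2Ser5, 0.41 for Pol2Ser2 and 0.98 for TotalRNAPol2.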

Other observations

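The windows, tests and sites in this part were chosen after the results were seen, except that the tests of copy number at the segments, of the authors' line in A for RAD21 and of RAD21 mean level were set before their results were seen.

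Of 7739 windows of 100 kb with at least 3 regions in each of the H3K27Ac, Pol2Ser5, Pol2Ser2 and TotalRNAPol2 tables, 135 had a median M of 1 or more in all 4 tables and 147 had -1 or less in all 4. With the windows of each table moved along the genome by a random distance, at most 5 and 3 windows did so in 1000 trials. Under constant centring the counts were 75 and 237, and with M recentred on all regions 118 and 168. The strongest gain lay at 29.2 to 29.3 Mb of chromosome 14, with a median M of 6.16 for H3K27Ac, 3.35 for Pol2Ser5, 3.09 for Pol2Ser2 and 3.39 for TotalRNAPol2, and CTCF at 1.81. At 57.0 to 57.1 Mb of chromosome 19 the medians were 4.94, 3.21, 2.79 and 3.07. Of the 5 strongest losses, 4 lay on chromosome 4 and 1 on chromosome X. At 104.4 to 104.5 Mb of chromosome 4 the medians were -4.35 for H3K27Ac, -3.73 for Pol2Ser5, -3.21 for Pol2Ser2 and -2.65 for TotalRNAPol2, while CTCF stood at -0.51 over 5 regions, RAD21 at -0.64 over 8 and SMC1 at 0.46 over 5.

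The share of CTCF regions higher in DKO varied along the genome. The windows named here are the extremes, and no shuffled or rescaled value was computed for them. Among 1315 windows of 1 Mb with at least 50 CTCF regions, the median share of regions higher in DKO was 16.2%. The share reached 55 of 60 regions (91.7%, 81.9% to 96.4%) at 59 to 60 Mb of chromosome 20, 54 of 63 (85.7%, 75.0% to 92.3%) at 31 to 32 Mb of chromosome 19 and 44 of 52 (84.6%, 72.5% to 92.0%) at 34 to 35 Mb of chromosome 16, and 0 regions were higher in HCT116 in these 3 windows. At 50 to 51 Mb of chromosome 13, in the segment where all targets were lower, 0 of 56 regions were higher in DKO (Wilson interval up to 6.42%) and 28 were higher in HCT116.

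The libraries titled TotalRNAPol2 resembled Pol2Ser5, the antibody their label names, more than Pol2Ser2 did. Across overlapping regions, which are not independent replicates, the Spearman rho of reads between Pol2Ser5 and TotalRNAPol2 was 0.84 in DKO and 0.77 in HCT116, against 0.61 and 0.50 between Pol2Ser2 and TotalRNAPol2 and 0.46 and 0.30 between Pol2Ser5 and Pol2Ser2.

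The excess of CTCF regions higher in DKO is in line with wider CTCF binding in cells with less DNA methylation, a hypothesis that these tables do not test since methylation was not analysed here. Counting error is argued against, as it would give 538 regions rather than 34479. With the tables' median shift in 865 bins of 2 Mb removed, the DKO to HCT116 ratio of region counts was 3.18. That shift came from regions called in both lines, whose median CTCF M the centring puts near 0 (0.008). A shift of most of the genome was thus not removed. The ratio argues against copy number shifts of these bins, relative to the rest of the genome, as the whole source. Bins with too few regions were not corrected and changes smaller than 2 Mb were not tested, so copy number stays open there. The authors' centring stays open: with the median of all regions set to 0 the ratio fell to 1.31, above equal numbers but well under 3.17, while constant centring raised it to 5.07. Regions called in 1 line only, 70937 in DKO and 25982 in HCT116, enter these ratios, and among regions called in both lines the ratio was 1.49. The level of no change cannot be told apart from a shift of all regions, nor can a difference between single libraries be from one between the lines.

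The segments on chromosomes 13 and 20 where all 7 targets shifted together may be differences in copy number between the lines. The median of the rest of the chromosome in the segment's direction was at most 0.18. Since the segments were chosen after their values were seen, this does not test the authors' centring. Copy number would shift regions called in 1 line only as well, and in 28 of 28 combinations of segment, table and calling line the median inside the segment lay on its side of the rest of the chromosome. Regulation of a whole segment would do the same and was not tested, since the input libraries were not used here.

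The M of RAD21 was lower where a similar CTCF region overlapped acetylation or polymerase (median -0.18 over 30721 regions) than where it did not (0.29 over 20218). The authors' line in A is argued against, as the difference was -0.58 with constant centring against -0.47 as deposited. A property of the RAD21 libraries alone is argued against as the whole source at these similar CTCF regions, since SMC1 showed a difference of -0.22 there, but it stays open for the larger size in RAD21, and at CTCF regions higher in HCT116 SMC1 stood at -0.61 with and -0.66 without such overlap, against -0.82 and -0.67 for RAD21. A higher level at such regions is argued against as well: in 4 equal classes of RAD21 mean level the difference was between -0.72 and -0.21, where that explanation allows at most 0.1 in size. Neither a difference in cohesin at active CTCF sites between the lines nor another response of the immunoprecipitations to open chromatin was tested, and both stay open, as does the level of no change, so that only the difference between these classes of regions is read.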
